A study of Mus musculus with 12 samples.

How the data were processed

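RNA expression was measured in snap-frozen liver of 12 mice, 3 in each of 4 groups made by genotype label (wild type or liver-specific Sirt6 knockout) and feeding (pair-fed or ethanol-fed). Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 µg of total RNA with a TruSeq RNA kit. The submitters' processing notes name STAR 2.5, featureCounts of Subread 1.5.3, edgeR 3.20.8 and the mouse build mm10. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

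The authors deposited 1 table with whole-number read counts per gene and library, which are not normalised per the file headers. The deposited log2 values are log2 CPM per library and, per the file headers, log2 fold changes of the authors' own genotype comparisons. The deposited log2 CPM were matched by TMM-normalised values with a prior count of 0.25, with a largest difference of 7.59e-06. The deposited p-values and FDR values belong to the authors' 2 genotype comparisons, and which edgeR test gave them is not given in the sources used here. The authors' gene Length column gives exonic length in bases, as featureCounts writes it. Coordinates are those of the table, on mm10.

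All 13097 genes in the table passed edgeR's filterByExpr for the 4 groups, so genes with fewer reads are not analysed here. Total counts ranged from 17305141 to 18279809 per library, and a count of 3 over a group was used as the floor below which no fold is given. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 12.9 to 114), so each was kept as 1 replicate, and the series' design text states that samples came from individual mice.

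Counts were normalised with TMM and tested with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood fits with robust dispersion over all 12 libraries and 1 coefficient per group (8 residual degrees of freedom). The 5 contrasts were ethanol-fed over pair-fed in each genotype label, labelled knockout over wild type in each feeding condition, and their interaction. Adjusted p is Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05, and the standard error is the log2 fold change over the square root of the F statistic. Means ± SD are of TMM-normalised CPM.

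Before the data were examined, 50 gene lists of liver pathways, stress responses and cell type markers were fixed, with 683 genes, of which 603 were in the table and 80 were not. The 45 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjusted p over the 45 lists, and again with an estimated correlation and with fry. The contrasts, the tests, the list of alternatives and the rule for naming genes were fixed at the same point. For each contrast that rule takes the 10 largest rises and the 10 largest falls past an adjusted p of 0.05. Such genes needed a mean of at least 1 CPM over the 12 libraries and 3 values of 1 group all outside the range of the other, except for the interaction. Clone or predicted names and antigen receptor segments were left out. It adds up to 4 members of each list with the smallest p, and 39 genes named in advance, of which Tnf, Timp1 and Cidea are not analysed here. Not every gene the rule takes is described, and results of some genes are not reported here. Overlaps of calls are given beside the product of both list sizes over the number of genes tested.

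Tested on counts simulated from the real genes' means and dispersions and the library sizes, the procedure was given 200 genes changed by known folds and 1 list shifted 2-fold in each contrast, and between 12943 and 12963 simulated genes passed the filter. All 200 were drawn from genes with a mean of at least 1 CPM, so the shares recovered do not cover genes with fewer reads. PCR reads carry no molecular identifiers here, so floors cover counting error only, whereas standard errors and the interval of Sirt6 come from the fit and cover the spread between mice. Genes changed 2-fold were recovered in 54% of cases for ethanol in wild type, 72% for ethanol in mice labelled knockout, 70% and 76% for genotype in pair-fed and ethanol-fed mice, and 24% for the interaction. At 4-fold the shares were 92%, 90%, 96%, 94% and 86% in the same order. Calls on unchanged genes made up 8.4%, 3.6%, 3.1%, 9.6% and 4.3% of the calls in that order. Every simulated group had the same spread per gene. In the real wild type and labelled knockout groups the biological coefficient of variation was 0.117 and 0.114 when pair-fed and 0.271 and 0.224 when ethanol-fed. The shares therefore do not give recovery or false calls under that unequal spread.

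Gene results were recomputed with median-of-ratios size factors, with total counts only and with a filter of at least 1 CPM in 6 libraries. They were also recomputed with DESeq2 1.42.0, with limma-voom and with only the 2 groups compared. Further alternatives were the mouse number as a block and leaving out each library in turn. List tests were recomputed only with median-of-ratios size factors, with the block and without each library in turn. The agreement of fold changes was not recomputed with the stricter filter, the block or only the groups compared. The authors' fold changes were used only to set their calls beside those made here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.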

Results

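Liver RNA was sequenced from 12 female C57BL/6 mice aged 3 months. The mice were wild type or labelled as liver-specific knockouts of Sirt6, which encodes an NAD-dependent deacylase of chromatin. Mice of each genotype were either pair-fed an isocaloric control diet or fed a Lieber-DeCarli liquid diet with 5% ethanol for 10 days and then given a single binge of ethanol at 5 g/kg, a common mouse model of alcoholic liver injury. Below, ethanol feeding stands for the diet and the binge together, whose effects cannot be told apart with these groups. Each of the 4 groups held 3 individual mice. Total counts per library ranged from 17305141 to 18279809 over 13097 genes. The comparisons asked how ethanol feeding altered liver transcripts in each genotype, how the genotypes differed under each feeding condition, and whether the ethanol response depended on genotype. Log2 fold changes are given as the estimate ± its standard error with n = 3 mice per group, and levels as TMM-normalised CPM ± SD.

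Feeding was the main axis of variation. The first principal component held 51.4% of the variance and separated the 6 ethanol-fed from the 6 pair-fed libraries, and the second held 14.7% and was positive in the 6 wild type libraries and negative in the 6 labelled knockout. Transcripts of Alb, which encodes the main plasma protein made by hepatocytes, took 11 to 12.7% of all counts in pair-fed libraries and 6.1 to 9.55% in ethanol-fed libraries. The biological coefficient of variation was 0.117 and 0.114 in the wild type and labelled knockout pair-fed groups, and 0.271 and 0.224 in the matching ethanol-fed groups. Scaling by total counts in place of TMM moved the median log2 fold change of all genes under ethanol from 0.03 to 0.18 in wild type mice and from 0.04 to 0.14 in mice labelled knockout, so changes are given relative to the TMM centre. The median of every list called below kept its sign under TMM, median-of-ratios and total-count scaling.

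**Figure D1:**
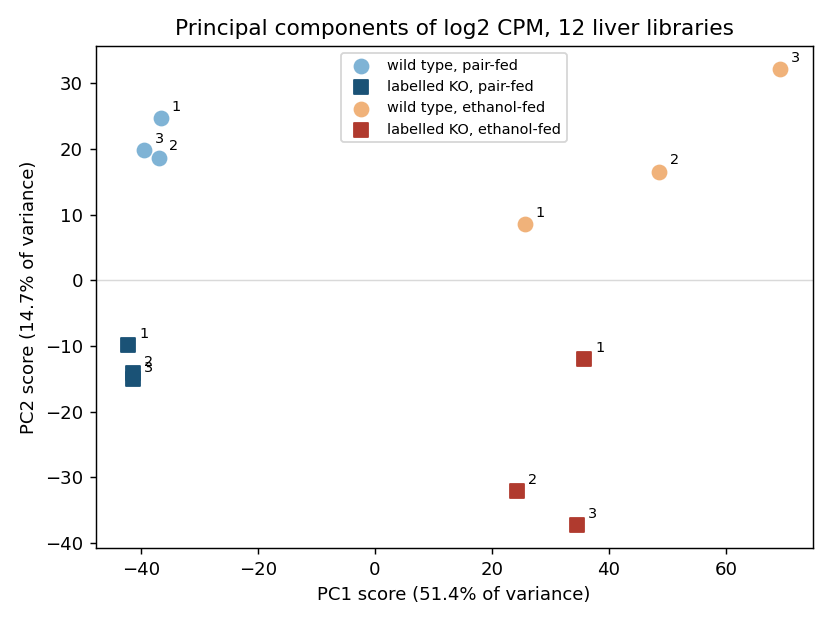
Scores of the 12 liver libraries on the first principal component (x axis, 51.4% of the variance) and the second (y axis, 14.7%) of log2 CPM. Colours and shapes mark the 4 groups and the digits are mouse numbers. Ethanol-fed libraries lie to the right of 0 on the x axis and libraries labelled knockout below 0 on the y axis.

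Sirt6 (chr10:81621786-81627608, mm10) was not lower in the libraries labelled knockout. Its counts were 51, 49 and 68 in wild type pair-fed mice and 52, 46 and 47 in pair-fed mice labelled knockout. In ethanol-fed mice they were 67, 54 and 60 in wild type and 53, 58 and 62 in mice labelled knockout. The log2 difference between genotypes was -0.23 ± 0.21 in pair-fed and 0.01 ± 0.21 in ethanol-fed mice, with an average of -0.11 ± 0.15 (95% interval -0.40 to 0.19), so that Sirt6 stood at 93.3% of the wild type level. Counts were given per gene and not per exon, and the exons targeted by the deletion are not given in the sources used here. Loss of some exons would lower such a total only by their share of its reads, and that share is not known here. Because the target transcript did not go with the label, the 6 libraries are called "labelled knockout" throughout, and every direction between genotypes below rests on that label.

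**Figure D2:**
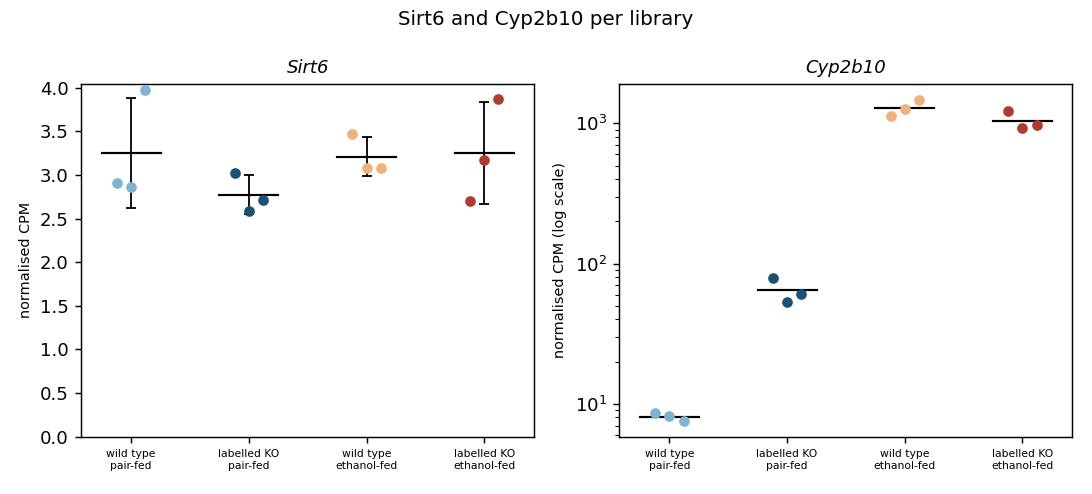
Normalised CPM of Sirt6 (left, linear axis from 0) and Cyp2b10 (right, log axis) in each library, by group. Points are mice, horizontal lines are means of n = 3, and error bars on the Sirt6 panel are SD. Sirt6 was alike under both genotype labels, and pair-fed Cyp2b10 was higher in all 3 libraries labelled knockout.

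In wild type mice, ethanol feeding raised Cyp2b10, a xenobiotic cytochrome P450 induced through the constitutive androstane receptor, from 8.11 ± 0.480 to 1287 ± 172 CPM (log2 fold change 7.31 ± 0.22, adjusted p = 7.64e-10). Atf3, a stress-induced transcription factor, rose from 1.97 ± 0.404 to 298 ± 283 CPM, and Trib3, a pseudokinase target of the integrated stress response, rose from 8.52 ± 1.31 to 390 ± 285 CPM. The zinc-binding metallothioneins Mt1 and Mt2 rose by 3.58 ± 0.45 and 4.55 ± 0.60 on the log2 scale. Cyp2e1, the ethanol-oxidising microsomal P450, fell from 11908 ± 975 to 4599 ± 1243 CPM (log2 fold change -1.37 ± 0.19, adjusted p = 0.000309), and AW549542 fell as well (log2 fold change -4.19 ± 0.23). In all, 4380 of 13097 genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 2480 higher and 1900 lower, and 1763 of these changed by at least 2-fold. Higher genes made up 56.6% of the calls with TMM and 74.1% with total counts. Without 1 library at a time the count ranged from 3023 to 4884.

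Several stress-response lists were called higher in wild type ethanol-fed livers. The heat shock response was not called (2 of 9 rose and 1 fell, the same adjusted over the list alone, median -0.27, camera adjusted p = 0.580). Of 19 NRF2 targets, a list of oxidant-responsive detoxification genes, 13 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 7.78e-09, and adjusted p = 0.175 with an estimated correlation). Srxn1, which reduces oxidised peroxiredoxins, rose by 3.57 ± 0.23 and the haem-degrading enzyme Hmox1 by 2.72 ± 0.31. Gsta1 and Gstm3, members of glutathione transferase families whose reads may be shared between copies, rose by 4.97 ± 0.48 and 3.93 ± 0.31 and are uncertain as single genes. Of 19 genes of ER stress and the integrated stress response, 9 rose and 0 fell, as many when adjusted over the list alone (camera adjusted p = 3.08e-05, and adjusted p = 0.175 with an estimated correlation); the amino acid synthase Asns rose by 3.96 ± 0.35 and the proapoptotic factor Ddit3 by 4.32 ± 0.56. Of 7 metallothionein and zinc genes 5 rose and 0 fell, as many when adjusted over the list alone (camera adjusted p = 0.00437, and adjusted p = 0.175 with an estimated correlation). Of 14 immediate early genes 9 rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 0.000431, and adjusted p = 0.323 with an estimated correlation), among them Jun by 3.00 ± 0.47 and Jund by 2.05 ± 0.27. Of 17 genes of the p53 and DNA damage response 7 rose, and 9 when adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.175 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 3.53 ± 0.59 and Gadd45a by 5.15 ± 0.75.

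Not all defence enzymes rose. Of 19 antioxidant enzymes 9 fell and 3 rose, and 10 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.0300, and adjusted p = 0.788 with an estimated correlation). Cat, the peroxisomal catalase, had a log2 fold change of -1.21 ± 0.17, extracellular superoxide dismutase Sod3 of -0.94 ± 0.14 and the mitochondrial Sod2 of -0.52 ± 0.12. Of 19 xenobiotic P450 genes and their receptors 9 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.000431, and adjusted p = 0.323 with an estimated correlation). Cyp2c29 rose by 1.73 ± 0.20, with reads that may be shared among Cyp2c copies. Of 11 genes of alcohol and acetaldehyde metabolism 8 fell and 0 rose, as many when adjusted over the list alone (camera adjusted p = 0.000267, and adjusted p = 0.175 with an estimated correlation). These included the alcohol dehydrogenase Adh4 (-1.55 ± 0.16), the fatty aldehyde dehydrogenase Aldh3a2 (-0.82 ± 0.16) and Cyp2e1, whereas Adh1, the main hepatic alcohol dehydrogenase, had a log2 fold change of -0.09 ± 0.15 (adjusted p = 0.690) and of 0.06 with total counts.

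Lipid synthesis genes were lower. Of 16 fatty acid synthesis genes 12 fell and 0 rose, and 14 fell when adjusted over the list alone (camera adjusted p = 3.53e-09, and adjusted p = 0.175 with an estimated correlation). The desaturases Fads1 and Fads2 had log2 fold changes of -1.08 ± 0.12 and -1.91 ± 0.16, ATP citrate lyase Acly of -2.19 ± 0.33 and the lipogenic transcription factor Srebf1 of -1.91 ± 0.30. Of 24 cholesterol synthesis genes 15 fell and 0 rose, and 16 fell when adjusted over the list alone (camera adjusted p = 7.37e-09, and adjusted p = 0.261 with an estimated correlation). Acat2, a cytosolic acetoacetyl-CoA thiolase, changed by -2.15 ± 0.24. Of 25 PPARA targets and genes of fatty acid oxidation 11 fell and 3 rose, and 13 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.00499, and adjusted p = 0.799 with an estimated correlation). The nuclear receptor gene Ppara itself changed by -1.94 ± 0.20, while the hepatokine Fgf21 rose by 3.58 ± 0.78. Among 14 lipid droplet and triglyceride genes 5 rose and 3 fell, with 5 and 4 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.729). Its rises included the droplet fusion protein Cidec by 5.48 ± 0.90 and the hypoxia-inducible droplet protein Hilpda by 3.11 ± 0.62. Lipg, the endothelial lipase, and Pnpla3, a lipid droplet acyl hydrolase, were among the largest falls named, at -3.75 ± 0.52 and -3.13 ± 0.51.

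Of 16 sirtuin and NAD metabolism genes 6 fell and 1 rose in wild type mice, and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0180, and adjusted p = 0.344 with an estimated correlation). Nampt, the rate-limiting enzyme of NAD salvage, changed by -1.10 ± 0.13 and the mitochondrial deacetylase Sirt3 by -0.69 ± 0.14. Of 13 pericentral hepatocyte genes 5 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.265 with an estimated correlation). Inflammatory mediators were not called as a list (8 of 15 rose and 2 fell, 9 and 2 adjusted over the list alone; camera adjusted p = 0.384); the endotoxin co-receptor Cd14 rose by 2.73 ± 0.43 and the adhesion molecule Icam1 by 1.04 ± 0.19. Interferon-stimulated genes, of which 8 of 20 rose and 2 fell (10 and 2 adjusted over the list alone), were not called either (camera adjusted p = 0.138). Among markers of other cell types, 3 of 10 T and NK cell markers fell, as many when adjusted over the list alone (camera adjusted p = 0.0597), and the 12 Kupffer cell and macrophage markers had a median log2 fold change of -0.26 (camera adjusted p = 0.287). Of the 45 lists, 13 were called with the preset correlation and 0 with an estimated one, while fry called 17. Leaving out 1 library ended the call of the antioxidant list in 3 of the 12 leave-outs and of the PPARA list in 2.

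**Figure D3:**
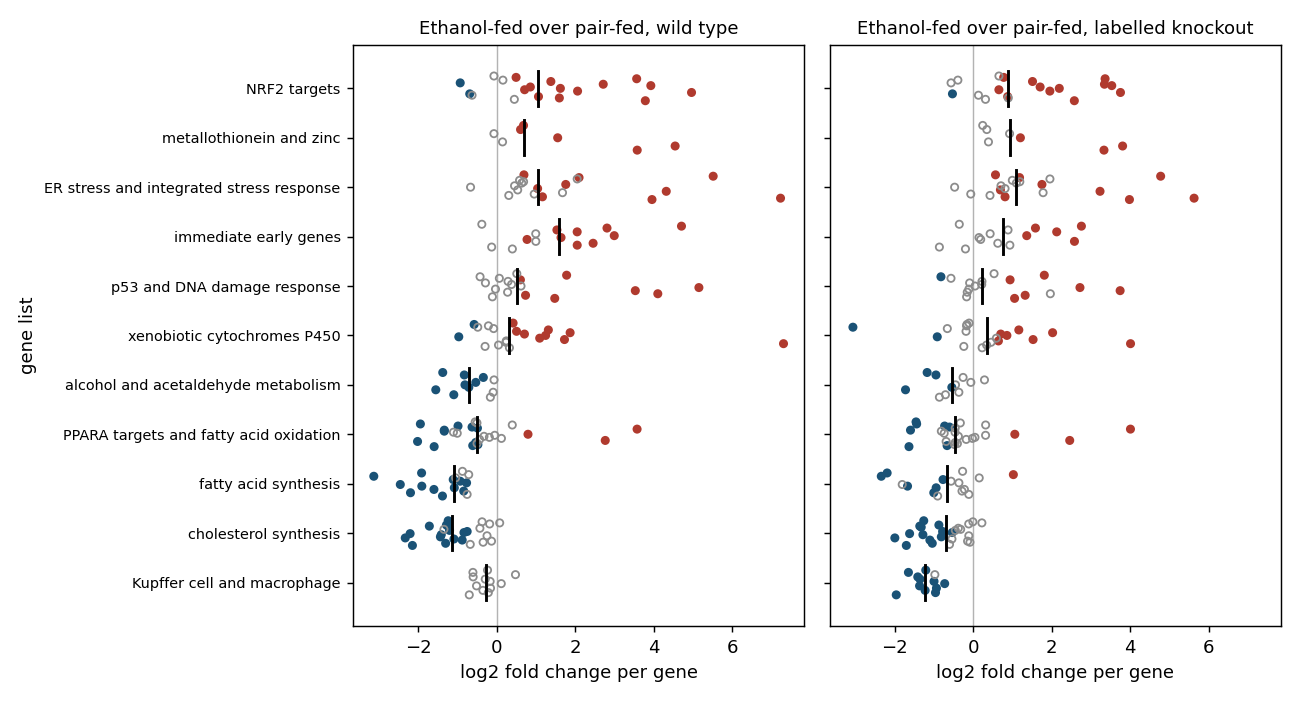
Log2 fold changes of ethanol-fed over pair-fed mice (x axis) for the members of 11 gene lists (y axis) in wild type (left) and labelled knockout (right) mice. Each point is a gene, red and blue points passed an adjusted p of 0.05 as higher and lower, open points did not, and vertical bars are list medians. Of 12 Kupffer cell and macrophage markers, 11 fell in mice labelled knockout.

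In mice labelled knockout, ethanol feeding raised Cyp2b10 from 64.5 ± 13.5 to 1039 ± 164 CPM (log2 fold change 4.01 ± 0.19, adjusted p = 2.15e-07). Atf3 rose from 2.48 ± 1.04 to 123 ± 59.2 CPM and Cidec from 2.01 ± 0.335 to 52.1 ± 19.6 CPM. Fst, which encodes the activin-binding hepatokine follistatin, rose by 4.70 ± 0.52, and Dusp8, a phosphatase of stress-activated kinases, by 4.60 ± 0.52. Upp2, a uridine phosphorylase, fell from 556 ± 53.5 to 55.4 ± 10.1 CPM (log2 fold change -3.33 ± 0.42, adjusted p = 0.000531). Lipg and AW549542 fell too, with log2 fold changes of -3.55 ± 0.52 and -4.35 ± 0.23. In all, 3222 genes changed, 1794 higher and 1428 lower, and 1277 of these by at least 2-fold. Higher genes made up 55.7% of the calls with TMM and 69.9% with total counts. The count fell to 2133, 1853 and 2089 without labelled knockout pair-fed mouse 1, 2 or 3.

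Several stress and detoxification lists were called higher in this genotype as well. The heat shock response again was not (3 of 9 rose and 1 fell, the same adjusted over the list alone, median -0.11, camera adjusted p = 0.817). Of 19 NRF2 targets 12 rose and 1 fell, and 14 and 2 when adjusted over the list alone (camera adjusted p = 1.36e-12, and adjusted p = 0.0801 with an estimated correlation), with Srxn1 at 3.36 ± 0.22 and Hmox1 at 3.35 ± 0.32. Of 19 ER stress genes 9 rose and 0 fell, as many when adjusted over the list alone (camera adjusted p = 1.43e-05, and adjusted p = 0.159 with an estimated correlation), with Asns at 3.98 ± 0.36 and Trib3 at 4.78 ± 0.65. Of 7 metallothionein and zinc genes 3 rose, and 6 when adjusted over the list alone (camera adjusted p = 0.00131, and adjusted p = 0.159 with an estimated correlation), with Mt1 at 3.33 ± 0.45. Of 14 immediate early genes 5 rose and 0 fell, the same when adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.532 with an estimated correlation). Of 17 p53 and DNA damage genes 6 rose and 1 fell, and 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0397, and adjusted p = 0.263 with an estimated correlation); Cdkn1a rose by 3.75 ± 0.60 and the proapoptotic Bbc3 by 1.33 ± 0.16. Of 19 xenobiotic P450 genes 7 rose and 2 fell, and 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.492 with an estimated correlation).

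Several metabolic lists were called lower in mice labelled knockout under ethanol. Others had positive medians and were not called: lipid droplet and triglyceride (0.43, camera adjusted p = 0.0981), urea cycle and ammonia (0.69, camera adjusted p = 0.139) and the methionine and one-carbon cycle (0.30, camera adjusted p = 0.201). Of their 14, 9 and 17 members 7, 3 and 7 rose and 2, 0 and 2 fell. Adjusted over the list alone, 7, 4 and 7 rose and 2, 0 and 3 fell. Of 11 alcohol and acetaldehyde genes 4 fell and 0 rose, and 5 fell when adjusted over the list alone (camera adjusted p = 0.000336, and adjusted p = 0.263 with an estimated correlation), with Adh4 at -1.72 ± 0.16 and Cyp2e1 at -1.17 ± 0.19. Of 16 fatty acid synthesis genes 6 fell and 1 rose, and 7 and 1 when adjusted over the list alone (camera adjusted p = 9.30e-05, and adjusted p = 0.287 with an estimated correlation), with Srebf1 at -2.19 ± 0.30 and Fads2 at -1.67 ± 0.16. Of 24 cholesterol synthesis genes 13 fell and 0 rose, the same when adjusted over the list alone (camera adjusted p = 1.21e-06, and adjusted p = 0.295 with an estimated correlation). Of 25 PPARA targets 7 fell and 3 rose, and 11 and 3 when adjusted over the list alone (camera adjusted p = 0.00973, and adjusted p = 0.692 with an estimated correlation). Of 16 sirtuin and NAD genes 3 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 0.0477, and adjusted p = 0.469 with an estimated correlation). Of 9 male-biased liver genes 4 fell and 0 rose, the same when adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.269 with an estimated correlation), among them the urinary protein Mup20 at -1.03 ± 0.21, with reads that may be shared between Mup copies. Of 19 circadian clock genes 7 fell and 4 rose, and 9 and 4 when adjusted over the list alone (camera adjusted p = 0.0180, and adjusted p = 0.263 with an estimated correlation), with the clock activator Arntl at 3.48 ± 0.46 and the clock output gene Tef at -1.30 ± 0.15. Of 21 cell cycle genes 7 fell and 0 rose, the same when adjusted over the list alone (camera adjusted p = 0.00609, and adjusted p = 0.441 with an estimated correlation), with the G1/S cyclin Ccne1 at -2.39 ± 0.35.

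Markers of resident immune cells fell in the same libraries. Of 12 Kupffer cell and macrophage markers 11 fell, as many when adjusted over the list alone, with a median log2 fold change of -1.22 (camera adjusted p = 1.12e-06, and adjusted p = 0.415 with an estimated correlation). The phosphatidylserine receptor Timd4 had a log2 fold change of -1.65 ± 0.31, the folate receptor Folr2 of -1.41 ± 0.32 and the complement subunit C1qb of -1.22 ± 0.28. Of 5 B and plasma cell markers 2 fell, and 4 when adjusted over the list alone (camera adjusted p = 0.00915, and adjusted p = 0.269 with an estimated correlation), with Ms4a1 (CD20) at -2.02 ± 0.50. Of 10 T and NK cell markers 3 fell, as many when adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.396 with an estimated correlation), with Nkg7 at -1.40 ± 0.38, a call lost without labelled knockout mouse 1 of the ethanol-fed (-1.31) or pair-fed group (-1.19). Of the 45 lists, 17 were called with the preset correlation and 0 with an estimated one, while fry called 18. A leave-out of 1 library ended the list call of the sirtuin list in 7 of the 12 leave-outs, of the p53 list in 3, of the immediate early list in 2 and of the PPARA list in 1.

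The ethanol responses of the 2 genotypes mostly had the same direction. Across the 13097 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.819 and Spearman's rho 0.800, and the 2 comparisons share no library. Genes higher under ethanol in both genotypes numbered 1411, where independent lists of these sizes would share 340, and genes lower in both numbered 1002 against 207. Only 4 genes were called in opposite directions, and 5036 of the 5185 genes called in either genotype had the same sign in both. The difference between the responses was tested directly as the genotype by ethanol interaction.

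In pair-fed mice, the label of knockout went with a set of large rises. Adgrv1, an adhesion G protein-coupled receptor gene (chr13:81095068-81633144), rose from 3.95 ± 0.832 to 310 ± 6.30 CPM (log2 fold change 6.29 ± 0.30, adjusted p = 3.72e-07). The imprinted fetal growth factor gene Igf2 rose from 0.677 ± 0.0725 to 78.9 ± 72.9 CPM, and its imprinted neighbour H19, a long non-coding RNA of fetal liver, from 11.2 ± 5.46 to 657 ± 337 CPM. The call of Igf2 was lost with only the 2 groups in the fit (log2 fold change 6.86). Cyp2b10 rose from 8.11 ± 0.480 to 64.5 ± 13.5 CPM (log2 fold change 2.99 ± 0.19, adjusted p = 3.63e-06). The semaphorin co-receptor Nrp2 changed by -1.63 ± 0.22, the organic cation transporter Slc22a3 by -1.72 ± 0.20, the transcriptional co-regulator Mn1 by -1.46 ± 0.17 and the non-coding Snhg11 by -3.85 ± 0.40. In all, 114 genes changed, 92 higher and 22 lower. The count was 253 with DESeq2 (172 higher and 81 lower), 481 with only the 2 groups in the fit (266 and 215). It was 48, 57 and 68 without wild type pair-fed mouse 1, 2 or 3, and 64 and 69 without labelled knockout pair-fed mouse 2 or 3. The authors' deposited table called 242 genes for this contrast, 168 higher and 74 lower, and held all 114.

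Male-biased liver genes were higher in the female mice labelled knockout. Of 9 such genes 4 rose and 0 fell, and 8 rose when adjusted over the list alone, with a median log2 fold change of 2.31 (camera adjusted p = 2.78e-29, and adjusted p = 0.000530 with an estimated correlation). Of the 11 genes fixed for this list, Cyp4a12a and Cyp4a12b are not analysed here. Cyp2d9, a male-specific steroid hydroxylase, rose from 74.9 ± 37.2 to 771 ± 93.5 CPM, Mup20 from 14.7 ± 1.93 to 72.8 ± 19.99 CPM and Mup7 by 6.41 ± 0.60 on the log2 scale. The Mup and Cyp2d families hold near-identical copies whose reads may be split by counting, so values of their single members are uncertain. Of 12 female-biased liver genes 0 rose and 0 fell, and 1 rose when adjusted over the list alone, and the list was not called (median 0.11, camera adjusted p = 0.734). Of 7 oncofetal genes 2 rose and 0 fell, Igf2 and H19, as many when adjusted over the list alone (camera adjusted p = 1.16e-08, and adjusted p = 0.0104 with an estimated correlation). These 2 lists were the only ones of 45 called with the preset and with an estimated correlation. The oncofetal list was not tested without the neighbours Igf2 and H19, and its median was 0.50 against a mean of 2.07.

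Other lists moved in pair-fed mice with few or no called members. All 16 fatty acid synthesis genes had negative log2 fold changes, with a median of -0.49 (camera adjusted p = 1.32e-07, and adjusted p = 0.267 with an estimated correlation), 0 called by edgeR, 2 adjusted over the list alone, 6 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. All 24 cholesterol synthesis genes were likewise negative, with a median of -0.44 (camera adjusted p = 1.32e-07, and adjusted p = 0.424 with an estimated correlation), 0 called by edgeR, DESeq2, limma-voom or adjusted over the list alone, and 7 at an unadjusted p under 0.05. Of 19 xenobiotic P450 genes 2 rose and 0 fell, and 4 rose when adjusted over the list alone (camera adjusted p = 0.000144, and adjusted p = 0.424 with an estimated correlation). The lists of NRF2 targets (median 0.29, camera adjusted p = 0.0135, and adjusted p = 0.496 with an estimated correlation), growth hormone and IGF1 axis (median 0.34, camera adjusted p = 0.0180, and adjusted p = 0.496 with an estimated correlation) and cell cycle (median 0.28, camera adjusted p = 0.0189, and adjusted p = 0.599 with an estimated correlation) were called higher. The methionine and one-carbon cycle was called lower (median -0.19, camera adjusted p = 0.0437, and adjusted p = 0.649 with an estimated correlation). Of the immune cell marker lists 3 were called higher in the same libraries. The T and NK cell markers were not called (median -0.10, 6 of 10 negative, camera adjusted p = 0.635). All 12 Kupffer cell and macrophage markers had positive values (median 0.43, camera adjusted p = 0.00216, and adjusted p = 0.723 with an estimated correlation), as did 5 of 5 B and plasma cell markers (median 0.58, camera adjusted p = 0.0435, and adjusted p = 0.501 with an estimated correlation). In both of these lists 0 members were called, over all genes or over the list alone. Among 9 monocyte and recruited macrophage markers 1 rose, the tetraspanin Cd9 by 1.29 ± 0.19, and 2 rose when adjusted over the list alone (camera adjusted p = 0.00343, and adjusted p = 0.267 with an estimated correlation). Leaving out 1 library ended the call of the B and plasma cell list in 6 of the 12 leave-outs, of the methionine list in 5, of the cell cycle list in 2 and of the growth hormone and Kupffer cell lists in 1 each. The 8 called lists with 0 called members held 123 genes, of which 27 had an unadjusted p under 0.05 in edgeR, and 3 were called by DESeq2 and 0 by limma-voom.

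**Figure D4:**
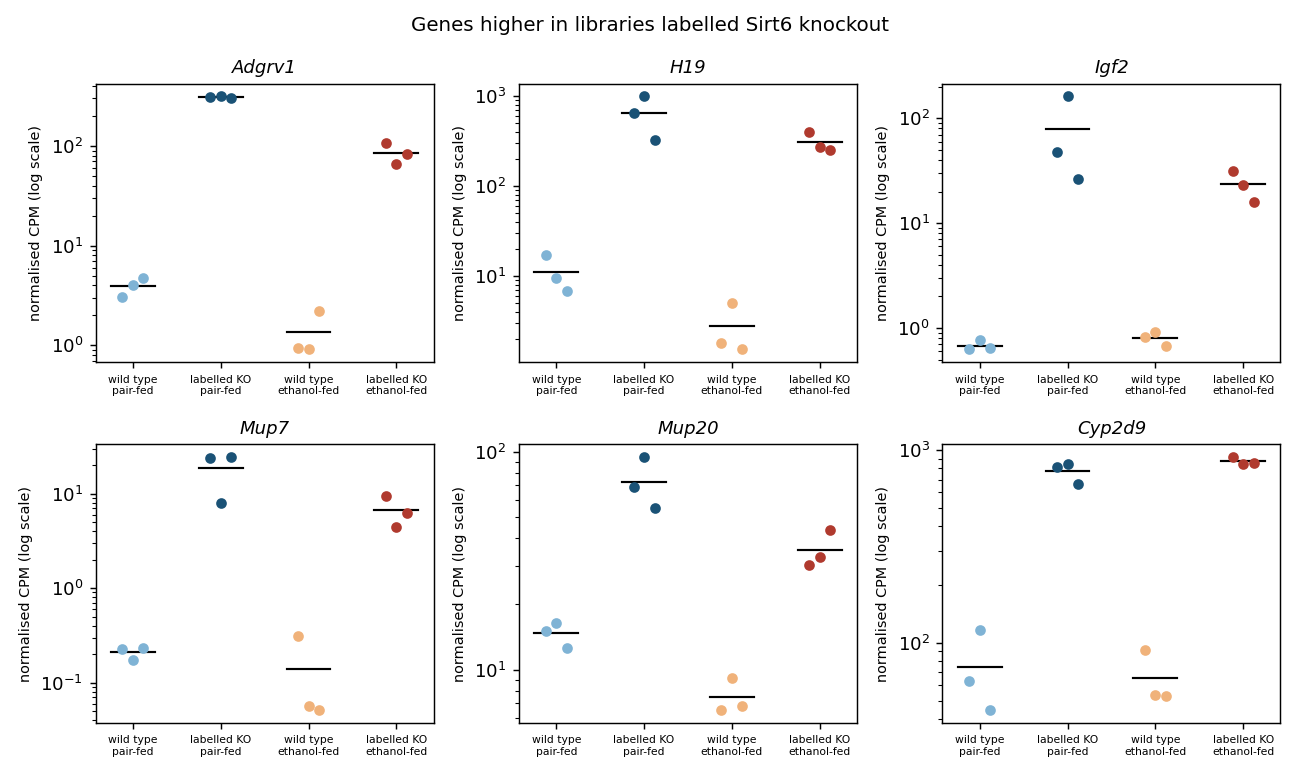
Normalised CPM (y axes, log scale) of Adgrv1, H19, Igf2, Mup7, Mup20 and Cyp2d9 in each library, by group. Points are mice and horizontal lines are means of n = 3. In both feeding conditions every mouse labelled knockout lies above every wild type mouse for each of the 6 genes. The rule for the largest rises requires such separation, so for genes it took this is no separate result.

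In ethanol-fed mice, Adgrv1 was again higher under the knockout label, at 85.3 ± 20.3 against 1.35 ± 0.741 CPM (log2 fold change 5.96 ± 0.31, adjusted p = 1.09e-06). H19 rose from 2.79 ± 1.93 to 310 ± 82.4 CPM and Igf2 from 0.802 ± 0.125 to 23.5 ± 7.70 CPM, though the call of Igf2 was lost without wild type ethanol-fed mouse 3 (log2 fold change 4.75). The transmembrane protease gene Tmprss4 rose by 4.31 ± 0.43 and Cd9 by 1.65 ± 0.19. Nrp2 fell from 63.2 ± 7.96 to 12.4 ± 1.67 CPM (log2 fold change -2.35 ± 0.22, adjusted p = 0.000175), and the membrane metallopeptidase Mme fell from 50.7 ± 4.08 to 12 ± 1.57 CPM. The leptin receptor Lepr, the clock repressor Nr1d1 and the stress-induced Sesn2 had log2 fold changes of -1.94 ± 0.37, -1.39 ± 0.26 and -1.07 ± 0.21, and all 3 calls were lost without wild type ethanol-fed mouse 2 or 3 or labelled knockout ethanol-fed mouse 2 or 3. Their values were then -2.05 to -1.64 for Lepr, -1.32 to -1.21 for Nr1d1 and -1.12 to -0.81 for Sesn2. The same 3 were lost with only the 2 groups in the fit, at -1.95, -1.40 and -1.07. In all, 148 genes changed, 99 higher and 49 lower. The count was 448 with DESeq2 (238 higher and 210 lower) and 47 with only the 2 groups in the fit (45 and 2). It was 697 (293 higher and 404 lower), 93 and 98 without wild type ethanol-fed mouse 1, 2 or 3. Without labelled knockout ethanol-fed mouse 1, 2 or 3 it was 288, 69 (61 and 8) and 72 (65 and 7). Setting wild type mouse 1 and labelled knockout mice 2 and 3 against the other 3 ethanol-fed mice called 373 genes, more than the 148 of the label. The authors' deposited table called 435 genes for this contrast, 244 higher and 191 lower, and held all 148.

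Of 9 male-biased genes 5 rose and 0 fell in ethanol-fed mice labelled knockout, as many when adjusted over the list alone (camera adjusted p = 4.69e-17, and adjusted p = 0.00400 with an estimated correlation). Cyp2d9 rose by 3.73 ± 0.33, Mup20 by 2.25 ± 0.22 and Mup7 by 5.49 ± 0.64. Hsd3b5, a male-specific steroid dehydrogenase on that list, had 0 counts in the wild type ethanol-fed mice and was near the floor under the knockout label, so no fold is given. Of 12 female-biased genes 1 rose and 0 fell, and 2 and 0 when adjusted over the list alone, and the list was not called (median 0.01, camera adjusted p = 0.594). The riser was the sulfotransferase Sult3a1, taken by the naming rule as the list member with the smallest p. Its log2 fold change was 4.23 ± 0.64 (adjusted p = 0.00990), a call lost without wild type ethanol-fed mouse 3 (4.05). Of 7 oncofetal genes 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 1.49e-06, and adjusted p = 0.0510 with an estimated correlation). Of 20 interferon-stimulated genes 19 had negative values, with a median of -1.02 (camera adjusted p = 4.32e-10, and adjusted p = 0.552 with an estimated correlation). Over all genes edgeR called 1 of them, DESeq2 13 and limma-voom 0, and 17 had an unadjusted p under 0.05 in edgeR. Adjusted over the list alone, 16 fell and 1 rose. The gene called by edgeR was the immunity-related GTPase Igtp, with a log2 fold change of -0.89 ± 0.20 (adjusted p = 0.0495). Its call was lost in 10 of the 12 leave-outs, at -0.96 to -0.67, and with total counts (-0.92), only the 2 groups in the fit (-0.90), the stricter filter (-0.89) and limma-voom (-0.87). The split of the ethanol-fed mice that called 373 genes was not tested on this list or on those that follow. In the same libraries all 12 Kupffer cell and macrophage markers were negative (median -0.48, camera adjusted p = 0.00896, and adjusted p = 0.936 with an estimated correlation), and all 7 cholangiocyte markers were positive (median 0.73, camera adjusted p = 0.000588, and adjusted p = 0.552 with an estimated correlation), with 1 and 3 called when adjusted over the list alone. The fibrosis and extracellular matrix list (median 0.61, camera adjusted p = 0.000699, and adjusted p = 0.816 with an estimated correlation), the NRF2 targets (median 0.30, camera adjusted p = 0.00430, and adjusted p = 0.552 with an estimated correlation) and the PPARA targets (median 0.28, camera adjusted p = 0.0475, and adjusted p = 0.936 with an estimated correlation) were called higher. The mesothelial cell markers, a cell type that also expresses matrix genes, were positive in 5 of 5 genes with 0 called over all genes or over the list alone (median 0.83, camera adjusted p = 0.122). The call of the PPARA list was lost in 8 of the 12 leave-outs, of the Kupffer cell list in 2 and of the NRF2 list in 1. The 5 called lists with 0 called members held 82 genes, of which 22 had an unadjusted p under 0.05 in edgeR, and 4 were called by DESeq2 and 0 by limma-voom.

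The genotype differences of the 2 feeding conditions shared 49 higher genes, where independent lists would share 0.695, and 7 lower genes against 0.0823. None was called in opposite directions, and 191 of the 206 genes called in either condition had the same sign in both. Across all genes, which are not independent replicates, Pearson's r was 0.491 and Spearman's rho 0.302, and the 2 comparisons share no library.

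Cyp2b10 was the 1 gene called by edgeR for an ethanol response that differed between genotypes, and genes not called are not shown to respond alike. Its interaction on the log2 scale was -3.30 ± 0.25 (adjusted p = 7.44e-05), a rise of 7.31 in wild type against 4.01 under the knockout label. The pair-fed level differed between genotypes, while the ethanol-fed level did not pass the test (log2 difference -0.31 ± 0.17, adjusted p = 0.413). At an unadjusted p under 0.05 there were 696 genes, and DESeq2 called 15 and limma-voom 1, with 20 and 2 by edgeR without wild type ethanol-fed mouse 1 or 3 and 2 without labelled knockout ethanol-fed mouse 1.

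As lists, 9 of 45 differed in their ethanol response with the preset correlation and 0 with an estimated one or by fry. The Kupffer cell and macrophage markers had a median interaction of -0.86, negative in 12 of 12 genes (camera adjusted p = 3.25e-09, and adjusted p = 0.515 with an estimated correlation), and the interferon-stimulated genes one of -0.99 (camera adjusted p = 3.88e-08, and adjusted p = 0.515 with an estimated correlation). Immediate early genes (-0.69, camera adjusted p = 0.00217, and adjusted p = 0.515 with an estimated correlation) and xenobiotic P450 genes (-0.10, camera adjusted p = 0.00121, and adjusted p = 0.515 with an estimated correlation) were also negative, the latter with Cyp2b10 as its called member. Positive medians were found for fatty acid synthesis (0.58, camera adjusted p = 6.59e-06, and adjusted p = 0.515 with an estimated correlation), cholesterol synthesis (0.26, camera adjusted p = 0.0163, and adjusted p = 0.654 with an estimated correlation), the methionine and one-carbon cycle (0.23, camera adjusted p = 0.00217, and adjusted p = 0.515 with an estimated correlation), fibrosis and extracellular matrix (0.43, camera adjusted p = 0.00217, and adjusted p = 0.615 with an estimated correlation) and pericentral hepatocyte genes (0.20, camera adjusted p = 0.0165, and adjusted p = 0.515 with an estimated correlation), the last with 1 member called when adjusted over the list alone. The mesothelial cell markers were positive in 5 of 5 genes beside the fibrosis list and were not called (median 0.90, camera adjusted p = 0.109). In the fatty acid list the stearoyl-CoA desaturase Scd1 at 1.74 ± 0.40 was called in edgeR over the list alone and not over all genes (adjusted p = 0.590). DESeq2 called it over all genes, at 1.72. The call of the cholesterol list was lost in 4 of the 12 leave-outs, of the fibrosis and pericentral lists in 2 each and of the methionine list in 1. The 8 of these lists with 0 called members held 135 genes, of which 27 had an unadjusted p under 0.05 in edgeR, and 1 was called by DESeq2 and 0 by limma-voom.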

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

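The interaction test was fixed in advance, and every other test in this part was chosen after the result was seen. The interaction test picked out 10 results as different between the ethanol responses of the 2 genotype labels. Cyp2b10 was the 1 gene, at -3.30 on the log2 scale. The other 9 were lists, called by camera with the preset correlation and given here by their medians, which camera does not test. They were lost with an estimated correlation, where camera's adjusted p ranged from 0.515 to 0.654. The list of xenobiotic cytochromes P450 holds Cyp2b10, so its call does not stand apart from that gene. The negative medians were -0.99 for interferon-stimulated genes, -0.86 for Kupffer cell and macrophage markers, -0.69 for immediate early genes and -0.10 for xenobiotic cytochromes P450. The positive medians were 0.58 for fatty acid synthesis, 0.43 for fibrosis and extracellular matrix, 0.26 for cholesterol synthesis, 0.23 for the methionine and one-carbon cycle and 0.20 for pericentral hepatocyte genes.

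Sirt6 counts were alike under both genotype labels. Over the genes called for the label in the other feeding condition, 0 of the 12 libraries lay nearer to the other label, which argues against single libraries swapped between the genotype labels. Depth too low to show a fall to 50% is argued against by the lower bound of the 95% interval of the mean log2 difference, -0.40, above the -1 that such a fall would give. Reads counted in exons outside the deleted part stay open: Sirt6 stood at 93.3% of wild type with 1 count per gene, and counts per exon are not analysed here. The lower bound of -0.40 limits how much of the total count the loss of some exons could have removed. A deletion of some exons that leaves the rest of the transcript is a candidate explanation, and a failed deletion in all 6 mice cannot be told apart from it with these counts.

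Male-biased liver genes were higher in female mice under the knockout label, and male mice under that label are argued against by Xist, which in each of the 6 libraries stood at 56.3% or more of the wild type mean under the same feeding. Genes linked to the targeted locus are argued against by position alone, since 0 of the 6 called male-biased genes lay within 20 Mb of Sirt6. That count follows from where the genes of the list lie and is no test of the label. Of all genes called for the label, 2 of 114 in pair-fed mice (1.75%) and 2 of 148 in ethanol-fed mice (1.35%) lay there. Of all genes tested, 2.22% did. Exchange of reads between copies of a family is argued against for Cyp2d9 in ethanol-fed mice, where the loss of the other Cyp2d genes was -4.83% of its gain (28.8% with 1 standard deviation). It stays open for Cyp2d9 in pair-fed mice (39.1%, or 83.7% with 1 standard deviation) and for Mup7 and Mup20, where the loss of the other Mup genes was 32.4% in pair-fed and -163% in ethanol-fed mice (248% and 124% with 1 standard deviation), although the other Mup genes called near them all rose, at log2 fold changes of 3.58 to 6.42 and 5.03 to 5.15. A loss of Sirt6 in hepatocytes stays open and was not tested, and of the 12 female-biased genes 0 were called lower, with medians of 0.11 in pair-fed and 0.01 in ethanol-fed mice.

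The rise of Cyp2b10 under ethanol was smaller under the knockout label, where its pair-fed level was higher. Reads shared with Cyp2b9 and Cyp2b13 are argued against: a share of their reads large enough to give the whole wild type pair-fed level would give at most 16.5% of the level in any pair-fed library labelled knockout. A single library is argued against by the highest adjusted p of the interaction without 1 library, 0.000966, in a range of 8.41e-30 to 0.000966 over all alternatives. Of 82 splits moving as many mice of each label in both feeding conditions, 10, the real one included, called at least 1 gene. The highest other count was 15. The other 9 all set wild type mouse 1 and labelled knockout mice 2 and 3 apart in the ethanol-fed group. That points to a structure of the samples. Every split but the real one mixes the labels, so genotype differences add to its spread, and those 9 share 1 ethanol-fed split. The number of genes with an interaction, 1, is therefore neither shown to be beyond chance nor shown to be chance. Higher activity of the receptor that induces Cyp2b10 in pair-fed mice labelled knockout is a candidate explanation that was not tested.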

How the results depend on the processing

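The agreement of fold changes between comparisons, and the alternatives of single named genes, were recomputed under settings chosen after seeing the data, and all other alternatives were fixed in advance. The number of genes changed by ethanol in wild type mice was within 1.5 times of 4380 under every alternative run, from 3023 to 4884 without 1 library. In mice labelled knockout it ranged from 1853 to 3867 without 1 library, with 2133, 1853 and 2089 without pair-fed mouse 1, 2 or 3 of that label. Genes changed by the knockout label in pair-fed mice numbered 253 with DESeq2, of which 112 were shared with the 114, and 481 with only the groups compared. Without 1 library they ranged from 48 to 151, with 48, 57 and 68 without wild type pair-fed mouse 1, 2 or 3 and 64 and 69 without labelled knockout mouse 2 or 3. In ethanol-fed mice the count was 448 with DESeq2, which held all 148, and 47 with only the groups compared. It ranged from 69 to 697 without 1 library, with 697, 93 and 98 without wild type mouse 1, 2 or 3 and 288, 69 and 72 without labelled knockout mouse 1, 2 or 3. For the interaction the count was 15 with DESeq2 and 1 to 20 without 1 library, with 20 and 2 without wild type ethanol-fed mouse 1 or 3 and 2 without labelled knockout ethanol-fed mouse 1. Falls without a library come with fewer samples, and the cause of the rises and of the other changes was not tested. The fit of all 4 groups shares 1 spread, with a coefficient of variation of 0.195. That lies above the 0.117 and 0.114 of the pair-fed groups and below the 0.271 and 0.224 of the ethanol-fed groups. With only the groups compared, genotype calls rose in pair-fed and fell in ethanol-fed mice, the direction these spreads would give.

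With a correlation estimated per list, the called lists numbered 0 and 0 for ethanol in the wild type and labelled knockout mice, 2 and 1 for the label in pair-fed and ethanol-fed mice, and 0 for the interaction, against 13, 17, 12, 8 and 9 with the preset. By fry they numbered 17, 18, 2, 2 and 0. Fry compares no list with other genes, and the cause of the other differences was not tested. Without 1 library the lists ranged from 11 to 14, 14 to 19, 8 to 13, 7 to 12 and 8 to 16 in that order. For the interaction they numbered 14 without wild type pair-fed mouse 1, labelled knockout pair-fed mouse 2 or wild type ethanol-fed mouse 3, 15 without wild type ethanol-fed mouse 2 and 16 without labelled knockout ethanol-fed mouse 1. Pearson's r between the ethanol responses ranged from 0.758 to 0.828 without 1 library, lowest without labelled knockout ethanol-fed mouse 1. Between the genotype differences it ranged from 0.440 to 0.509, lowest without wild type pair-fed mouse 1.

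With the mouse number as a replicate block, the gene counts were 3949, 2915, 99, 118 and 1 in the same order, and the list counts 14, 16, 12, 8 and 12. Under the block the named genes Lcn2 for ethanol in mice labelled knockout (2.78) and Igtp for the label in ethanol-fed mice (-0.89) were not called. The numbers do not pair the mice: of 18 pairs of same-numbered libraries 2 correlated above 0.1 (range -0.168 to 0.158), and 4 of 12 libraries matched their own number best in another group.

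Of 738 values of the 106 named gene results under other settings, 717 kept their direction and side of the threshold, 12 lost a call, 4 gained one and 5 changed sign. Of 1272 without 1 library these were 1235, 32, 2 and 3. No called gene changed sign. The changes of sign were those of Adh1 under ethanol in wild type (0.06 with total counts) and of Sirt6 between genotypes in ethanol-fed mice, neither of them called. For Sirt6 the log2 fold change was -0.01 with DESeq2 and with limma-voom, 0 with median-of-ratios size factors and -0.03 with total counts. Without 1 library it ranged from -0.13 to 0.13.

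A filter that keeps any gene with a read removed no gene, so it gave no other value. A pseudocount of 0.1, no filter on normalised values and quantile scaling were not run because the table holds counts, and the interaction needs all 4 groups. Depth limits genes with few reads. For the interaction a 2-fold change was recovered in 24% of simulated cases, which had the same spread in every group. Those cases were genes with a mean of at least 1 CPM, so the share does not cover genes with fewer reads.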

Other observations

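Genes in this part other than Saa1, Lcn2 and Ugt1a5 were chosen after their values were seen, as were the tests of placement, of gene length, of other splits and of the slopes of the ethanol response. Besides H19 and Igf2, another imprinted locus moved under the knockout label in ethanol-fed mice. Meg3, a maternally expressed long non-coding RNA (chr12:109540996-109571729, mm10), stood at 57.7 ± 6.13 CPM against 5.98 ± 4.26 in wild type (log2 fold change 3.27 ± 0.41, adjusted p = 0.00240), and Rian, downstream of it on the same strand, at 18.2 ± 3.04 against 2.14 ± 2.36 CPM (3.07 ± 0.55, adjusted p = 0.0198). In pair-fed mice the log2 fold change of Meg3 was 1.95 ± 0.43 (adjusted p = 0.0672), which passed the threshold with only the groups compared and, at 1.95 each, with DESeq2, with the stricter filter and without wild type ethanol-fed mouse 1 or 3. The call of Rian was lost without wild type ethanol-fed mouse 2 (2.70) and without labelled knockout ethanol-fed mouse 2 (3.21) or 3 (2.99), and with only the groups compared (3.07).

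Within the Ugt1a locus, whose glucuronosyltransferase transcripts share 3' exons and so share reads, Ugt1a9 rose in pair-fed mice labelled knockout (1.34 ± 0.20) while Ugt1a5 changed by -1.41 ± 0.19, and the values of both are uncertain as single genes. Ugt1a9 rose in ethanol-fed mice as well (1.37 ± 0.20), while Ugt1a5 (-0.92) and Ugt1a1 (-0.64) were called lower there, with the same uncertainty as single genes. The acute-phase gene Saa1 stood at 580.7 CPM in labelled knockout ethanol-fed mouse 3 and at 3.90 to 26.5 CPM in the other 11 libraries. Lcn2, a neutrophil and acute-phase protein gene, stood at 452.8 CPM in that mouse, and its ethanol call in mice labelled knockout (log2 fold change 2.86 ± 0.84, adjusted p = 0.0307) was lost without that mouse, at 1.07, and without labelled knockout pair-fed mouse 2 (2.79) or 3 (2.51). It was also lost with only the groups compared (2.84).

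Genes called for the knockout label lay near each other. In pair-fed mice 37 of 114 had another called gene within 500 kb, where 10000 random sets of like expression had a median of 12 and a highest of 31 (permutation p = 1e-04, the smallest these sets can give). In ethanol-fed mice it was 39 of 148, with a median of 19 and a highest of 48 (permutation p = 0.001). Of the called genes 17 and 20 carry names of the Mup, Serpina, Cyp2d, Ugt, Gst or Sult families, whose copies lie side by side and share reads. Those numbers are over all called genes, with or without a called neighbour. They leave out neighbours that share other family names, such as Ly6a with Ly6f in both feeding conditions and Cyp3a11 with Cyp3a59 in pair-fed mice. Called neighbours outside these families included Hc (0.75) with Gsn (1.18) in pair-fed mice and Meg3 (3.27) with Rian (3.07) in ethanol-fed mice. Others changed in opposite directions, such as Tbc1d30 (-1.06) with Rassf3 (1.06) in ethanol-fed mice. Nearness was not tested apart from the family copies, so how far it rests on them stays open.

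For the interaction, 24 of 100 splits drawn first from all 200 regroupings within feeding conditions, the real one included, called as many genes as the real one. That draw is no reference, since 59 of its splits carry the genotype effect into the contrast, among them the highest, 389, which exchanges all labels of the ethanol-fed mice.

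The 3 against 3 designs give 10 splits each, too few for a share under 0.05. The real splits called 4380, 3222 and 114 genes for ethanol in wild type, for ethanol in mice labelled knockout and for the label in pair-fed mice, where the highest other split called 0, so 1 split was as large in each. Every other split mixes the compared groups, so their difference adds to the spread within groups. A count of 0 there lends the real counts no support. For the label in ethanol-fed mice 2 splits were as large, the real one with 148 genes and another with 373. That split set wild type mouse 1 and labelled knockout mice 2 and 3 against the other 3 ethanol-fed mice and points to a structure among these libraries that genotype does not describe. Wild type mouse 1 and labelled knockout mice 2 and 3 had the lowest scores of the ethanol-fed libraries on the first principal component, 25.64, 24.22 and 34.46, against 35.76 in labelled knockout mouse 1 and 48.5 and 69.19 in wild type mice 2 and 3. The response of each ethanol-fed library was also expressed as its slope on the log2 fold changes of the genes called for ethanol in the other genotype. The slopes were 70.4%, 86.5% and 100.9% in wild type mice 1, 2 and 3 and 71.8%, 59.2% and 68.3% in labelled knockout mice 1, 2 and 3. The genotypes were measured on different genes, 3222 and 4380, and the difference between their slopes was not tested. Spearman's rho between log2 fold change and exonic length across genes, which are not independent replicates, ranged from -0.122 to 0.059 over the 5 contrasts.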
